A study of Mus musculus with 12 samples.

How the data were processed

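Ribosome-bound RNA and total RNA were compared in the ventromedial nucleus (VMN) of mouse hypothalamus by translating ribosome affinity purification (TRAP). In TRAP a GFP-tagged ribosomal protein is expressed in chosen cells, here SF1 cells, and their ribosomes are pulled down with the RNA they hold. There were 12 libraries from 6 pools of 6 animals. Each pool gave an input library, made from the dissected tissue, and an output library, made from the pulled-down RNA. Groups and replicate numbers were taken from the sample titles, which gives 3 libraries each of CTRL input, DN input, CTRL output and DN output. DN stands for a virus coding for a dominant-negative form of AMPK, a kinase that senses cellular energy.

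The values are counts of reads per Ensembl gene, deposited by the authors as 1 file per library with no normalization. All values were whole numbers, and 5 entries at the end of each file are HTSeq's classes of reads without a gene, which were left out of every total. Per the submitters' processing notes, cutadapt 1.3, STAR 2.4.2a, HTSeq 0.6.1 and genome build GRCm38 were used. Per the labels, all RNA was amplified with the NuGEN Ovation RNA-Amplification System before sequencing. The annotation release, the strand setting and the parameters of these tools are not given in the sources used here. Gene symbols, biotypes and positions came from GENCODE release 21 for mouse on GRCm38, which held 46005 of the 46517 identifiers (98.9%). No library was a copy of another. No molecular identifiers were named, so limits drawn from counts cover counting error only.

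Genes were tested with the quasi-likelihood method of edgeR 4.0.16 in R 4.3.3, two-sided, with TMM scaling, filterByExpr (minimum count 10, minimum total 15) and Benjamini-Hochberg adjustment over the genes tested at a threshold of 0.05. DN was compared with CTRL within outputs and within inputs, and output with input within CTRL and within DN, each in a fit of the 6 libraries concerned. The difference between these effects was an interaction term in a fit of all 12 libraries. Errors of fold changes are standard errors (SE) of the fitted log2 fold change. Levels are normalized CPM, counts scaled to library size, with TMM factors over the 12 libraries, given as mean and standard deviation (SD) of 3 libraries per group. Where all libraries of a group had 0 counts, a fold is given as a bound against 3 counts over the whole group. Log2 ratios of output to input within a pool used normalized CPM plus 1.

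Fixed before the data were examined were the groups, the tests, 42 gene lists on energy metabolism, stress, neuron types, neuronal function and other cell types, and the rule for named genes. Lists with at least 5 measured members were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, then with an estimated correlation and with fry, which tests whether members move one way. Camera p values were adjusted over the lists of a comparison. The rule for named genes took, per comparison, protein-coding genes past the threshold with every library of one group above every library of the other and a mean of at least 5 CPM in the higher group, and of these the 12 with the largest rise and the 12 with the largest fall. Where fewer than 6 genes passed, the 10 with the smallest unadjusted p were taken instead. Up to 4 members with the smallest p were taken from each list described. Prkaa1, Prkaa2, Rpl10a, Nr5a1, Txn2 and Fos were always included. Txn2 is remembered from the published study of these samples, so neither it nor its list is independent evidence. A few further list members, named where the count of a list was small, were chosen after their values were seen, as stated beside them.

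Input and output libraries of one number come from one pool. Deviations from the group means correlated across genes within a pool at r = 0.155, 0.056 and 0.219 in CTRL and at 0.019, -0.01 and 0.009 in DN. DN and CTRL pools are different animals that share only a number, so fits of DN against CTRL held no pool term. The output-input and interaction fits left it out too, although input and output of a pool are paired there. Fits with the pool as a block are given beside those results.

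Alternatives were DESeq2 1.42.0, limma-voom with sample weights, DESeq2 size factors and upper quartile scaling. Others were no filter on low counts, a mean of at least 5 CPM, a block, 1 fit of all 12 libraries, and leaving out each replicate. The block was the pool for output against input and in the interaction. Between DN and CTRL it was the replicate number, which joins unrelated animals, so no real pairing is tested there. Leaving out the genes of the mitochondrial chromosome was added after seeing the data. The tools were tested on simulated data with the spread of these libraries. Counts were drawn independently for each gene from a negative binomial model with the dispersions that edgeR estimated, which may favour edgeR. In simulated outputs of DN against CTRL, edgeR recovered 34.1% of 91 genes changed 4-fold and 3.16% of 95 genes changed 2-fold, with 1 false call among 35. At 50 CPM or more, edgeR recovered 89.7% of 29 genes changed 4-fold and 20% of 15 changed 2-fold. DESeq2 made 55 false calls among 113 in the same data, a share that need not hold in the real libraries. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.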

Results

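RNA was measured in the VMN of mice on chow after an overnight fast. All animals received, per the labels, a virus for a GFP-tagged ribosomal protein L10, and the DN animals also one for dominant-negative AMPK. The treatment text of the CTRL samples names the dominant-negative virus as well, while their characteristics say that they lacked it, and the characteristics were followed here. If CTRL animals had no second virus, effects of the construct and of a second virus cannot be told apart. RNA counts do not measure AMPK activity, so whether AMPK was blocked is not known from these libraries. The 12 libraries fell into 4 groups of 3, and total gene counts ranged from 34.6 to 55.5 M per library. Genes of the mitochondrial chromosome took 75.9% ± 1.09 (SD, n = 3) of the gene counts in CTRL inputs and 78.6% ± 1.03 in DN inputs. In outputs they took 22.4% ± 3.90 in CTRL and 24.9% ± 1.01 in DN. Nuclear genes therefore had 8.54 to 11.3 M counts in inputs and 26.2 to 32.1 M in outputs.

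**Figure D1:**
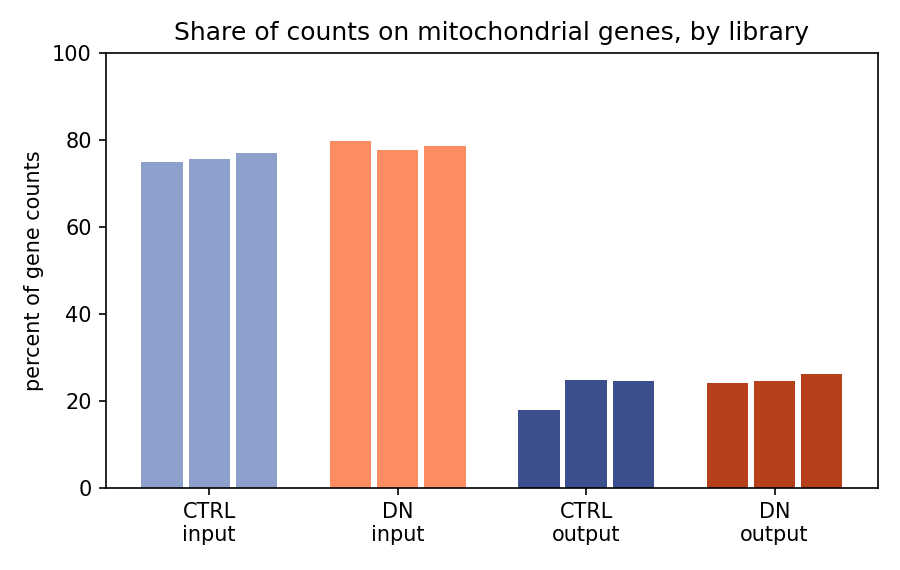
Percent of gene counts that fell on genes of the mitochondrial chromosome (vertical axis), 1 bar per library, in replicate order within each group. The 6 inputs lie between 74.9% and 79.7%, and the 6 outputs between 17.9% and 26.1%.

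The first question was which cells the pull-down captured in CTRL animals. CTRL outputs carried more RNA of VMN neurons and less RNA of glia, of other hypothalamic neurons and of mitochondria than the inputs of the same pools. Fezf1, a transcription factor of VMN neurons, rose from 17.3 ± 3.53 to 167 ± 8.37 CPM (log2 fold change 3.26 ± 0.21, SE). Nr5a1, the gene that encodes SF1 (ENSMUSG00000026751, chromosome 2, 38692656 to 38714542), rose from 2.07 ± 0.846 to 22.7 ± 12.2 CPM (3.44 ± 0.55, adjusted p = 0.00751). In the list of VMN neuron markers, 14 of 34 measured genes were higher in outputs, 1 was lower and 19 did not pass (21 and 2 adjusted over the list alone). The list rose in camera (adjusted p = 7.9e-17, and adjusted p = 0.0118 with an estimated correlation). Slc17a6, a vesicular glutamate transporter, rose by 1.20 ± 0.14, Gda, a guanine deaminase, by 1.80 ± 0.22, and Lmo3, a transcriptional cofactor, by 1.43 ± 0.19 on the log2 scale. The lower member was Dlk1, named after its value was seen, at -0.61 ± 0.14 with adjusted p = 0.0461. Calls of single genes in this list ended without 1 pool: adjusted p was 0.0516 for Slc17a6 without pool 1, 0.0523 for Gda and 0.105 for Lmo3 without pool 2, and 0.145 to 0.372 for Dlk1 without any of the 3 pools, whereas Fezf1 passed without each. Over all alternatives the adjusted p ranged from 5.42e-13 to 0.0516 for Slc17a6, 6.06e-13 to 0.0523 for Gda, 5.36e-11 to 0.105 for Lmo3 and 0.00207 to 0.372 for Dlk1.

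Lists of markers of other cells fell in the CTRL outputs. Of 18 astrocyte genes 13 were lower (17 adjusted over the list alone), and of 17 oligodendrocyte genes 11 were lower (14 over the list alone). Slc1a3, a glial glutamate transporter, went from 201 ± 28.4 to 33.8 ± 6.0 CPM. Both lists fell with camera (adjusted p = 2.04e-27 and 6.31e-23, and adjusted p = 0.0111 and 0.0238 with an estimated correlation). Of 12 genes of GABA neurons, 2 were lower (6 over the list alone), among them Gad2, an enzyme of GABA synthesis, at -1.46 ± 0.15. Of 12 genes of lateral and paraventricular hypothalamic neurons, 3 were lower (4 over the list alone), which were Pmch at -3.74 ± 0.42, Hcrt at -7.17 ± 1.22 and Avp at -3.17 ± 0.72, the precursors of melanin-concentrating hormone, orexin and vasopressin. These lists fell too (adjusted p = 1.96e-08 and 2.71e-08, and adjusted p = 0.0238 for each with an estimated correlation). Of 8 measured mitochondrially encoded genes 7 were lower (8 over the list alone), with a list median of -3.04 and mt-Cytb at -3.21 ± 0.19 (list adjusted p = 3.79e-64, and adjusted p = 0.0238 with an estimated correlation). Slc1a3 and mt-Cytb passed without each pool, whereas calls ended for Gad2 and Pmch without pool 2 (adjusted p = 0.0546 and 0.0599), for Hcrt without pool 1 or 2 (0.112 and 0.151) and for Avp without any of the 3 (0.121 to 0.265).

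The remaining 10 list calls in CTRL, 4 higher and 6 lower in outputs, rested on the preset correlation. Of 37 glutamate and GABA receptor genes 5 were higher (12 over the list alone), among them Gabra5 at 1.63 ± 0.15, Gabrb1 at 0.66 ± 0.13, Grin2b at 0.59 ± 0.12 and, named after its value was seen, Gria3 at 0.80 ± 0.18. Of 40 voltage-gated channel genes 5 were higher (8 over the list alone), among them Kcnq3, a potassium channel subunit, at 1.53 ± 0.14, Kcnb2 at 0.82 ± 0.18 and, named after its value was seen, Kcnh7 at 0.81 ± 0.18. The receptor and channel lists had adjusted p = 7.1e-06 and 7.54e-05, but adjusted p = 0.0526 and 0.201 with an estimated correlation. Pan neuronal genes and genes of vesicle release rose as lists (adjusted p = 0.00767 and 0.0405, but adjusted p = 0.35 and 0.163 with an estimated correlation), with Snap25, a protein of vesicle fusion, at 0.77 ± 0.12. The pan neuronal call ended without pool 1 (0.146), and the vesicle release call without pool 1 or 2 (0.191 and 0.104) and with DESeq2 size factors (0.0546). Oligodendrocyte precursors, microglia, endothelium, ependyma, glial activation, and arcuate and dorsomedial neurons fell as lists, with adjusted p between 2.71e-08 and 0.00436, but adjusted p = 0.0576, 0.206, 0.108, 0.108, 0.359 and 0.104 with an estimated correlation. C1qb, a complement protein of microglia, was at -3.89 ± 0.78 and Ghrh, growth hormone releasing hormone, at -4.19 ± 0.55, whereas Prlr, the prolactin receptor, rose by 1.31 ± 0.16. Gabra5 and Kcnq3 passed without each pool. Calls ended without pool 1 and without pool 2 for Snap25, Ghrh, Prlr and Gria3 (adjusted p = 0.0516 to 0.224), and without any of the 3 for Gabrb1, Grin2b, Kcnb2, Kcnh7 and C1qb (0.0713 to 0.302), with C1qb at -2.36 without pool 3.

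In all, 240 genes were higher and 191 lower in CTRL outputs among 13456 tested. With the pool as a block 527 genes passed and 400 of the 431 were shared. The block ended 7 calls of named genes, Avp among them (adjusted p = 0.0505, with a range over the alternatives from 1.52e-04 to 0.265), and added the interferon response list as lower in outputs (0.00618, against 0.139 without it). Without CTRL pool 1, 2 or 3 the number fell to 54, 45 or 214, of which 53, 44 and 181 were among the 431, and more genes were lower than higher (17 higher and 37 lower, 13 and 32, 100 and 114), so which direction held more genes is not settled. Nr5a1 had adjusted p = 0.165 without pool 1 and 0.108 without pool 2, with a range over the alternatives from 5.21e-09 to 0.165. The 2 groups were fully apart for 23.2% of genes, where chance gives 10%.

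The question was asked in the DN animals too, where outputs carried more RNA of VMN neurons and less of glia and mitochondria than inputs. Fezf1 rose from 23.5 ± 10.4 to 233 ± 32.2 CPM (3.30 ± 0.32) and Gtf2i, a general transcription factor, from 30.3 ± 12.2 to 471 ± 60.4 CPM (3.95 ± 0.27). Nr5a1 had 6.03 ± 1.15 CPM in DN inputs and 22.4 ± 10.4 in DN outputs (1.88 ± 0.55, adjusted p = 0.0946 by edgeR, but 0.0083 by DESeq2, in a range over the alternatives from 0.0083 to 0.422, higher in all 3 outputs). Of 34 VMN neuron genes 12 were higher (17 over the list alone) and 1 was lower, again Dlk1 at -0.66 ± 0.15. The list rose (adjusted p = 8.32e-13, and adjusted p = 0.0102 with an estimated correlation), with Slc17a6 at 1.43 ± 0.17, and of these genes Fezf1 and Slc17a6 passed without each DN pool while Dlk1 did not without any (adjusted p = 0.107 to 0.196). Of 17 astrocyte genes 12 were lower (17 over the list alone) and of 17 oligodendrocyte genes 11 (16 over the list alone), and both lists fell (adjusted p = 4.6e-29 and 4.12e-28, and adjusted p = 0.00363 for each with an estimated correlation). Slc1a2, a glial glutamate transporter, was at -1.30 ± 0.10.

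Further lists fell in the DN outputs. Of 15 glial and immune activation genes 7 were lower (9 over the list alone), with B2m, a subunit of class I histocompatibility molecules, at -1.67 ± 0.19, and of 15 microglia genes 3 were lower (8 over the list alone), which were Ctss at -3.61 ± 0.52, Itgam at -2.48 ± 0.55 and Csf1r at -3.11 ± 0.77. These lists had adjusted p = 3.25e-12 and 5.75e-10, and adjusted p = 0.0308 and 0.0293 with an estimated correlation. Mitochondrially encoded genes were lower at 7 of 8 (8 over the list alone), with a list median of -3.02 (adjusted p = 7.5e-94, and adjusted p = 0.00363 with an estimated correlation). Pmch at -3.89 ± 0.46 and Avp at -4.43 ± 0.86 were the 2 of 12 lateral and paraventricular genes that passed (8 over the list alone), and that list had adjusted p = 6.81e-08 (0.0293 with an estimated correlation). Bcas1 at -3.94 ± 0.63 and Pdgfra at -2.52 ± 0.58 were the 2 of 11 genes of oligodendrocyte precursors that passed (4 over the list alone). That list and endothelium fell (adjusted p = 4.42e-06 and 4.68e-05, and adjusted p = 0.035 and 0.0376 with an estimated correlation). Receptor genes, 9 of 36 (12 over the list alone), and channel genes, 4 of 39 (6 over the list alone), passed as higher, and both lists rose (adjusted p = 5.1e-05 and 1.01e-04, and adjusted p = 0.0376 and 0.0371 with an estimated correlation), with Kcnq3 at 1.34 ± 0.14 and Kcnh7 at 1.02 ± 0.19 among the channels. Another 9 lists passed at the preset correlation but had adjusted p between 0.0727 and 0.416 with an estimated correlation, among them GABA neurons with Gad2 at -1.76 ± 0.14 and pan neuronal genes with Syn1, a synaptic vesicle protein, at 1.04 ± 0.12. Of these 9, fatty acid oxidation and core histones no longer passed without DN pool 1 (0.266 and 0.0673) or 3 (0.123 and 0.0682), and arcuate and dorsomedial neurons without pool 1 or 2 (0.0646 and 0.0756). Pmch, Kcnq3, Gad2 and Syn1 passed without each DN pool, as did B2m, whose call ended in 1 fit of all 12 libraries (0.334, range over the alternatives 3.09e-14 to 0.334). Calls ended for Ctss without pool 3 (0.0575), for Bcas1 without pool 1 or 3 (0.0525 and 0.0692), for Itgam without pool 2 or 3 (0.211 and 0.197), and without any of the 3 for Csf1r, Avp, Pdgfra and Kcnh7 (0.0509 to 0.314), with Pdgfra at -1.61 without pool 2.

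In DN, 240 genes were higher and 201 lower in outputs among 13041 tested, and the groups were apart for 22.5% of genes, where chance gives 10%. With the pool as a block 396 genes passed, 353 of them shared with the 441. The block ended 8 calls of named genes, among them Pdgfra (adjusted p = 0.0628, range over the alternatives 7.81e-05 to 0.314) and Csf1r (0.0838, range 1.51e-04 to 0.309). Without DN pool 1, 2 or 3 the number was 148, 136 or 115. CTRL and DN shared 137 genes higher in outputs (4.60 expected by chance) and 100 lower (2.79 expected), and 0 genes called by edgeR in both went opposite ways among 12521 tested in both.

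**Figure D2:**
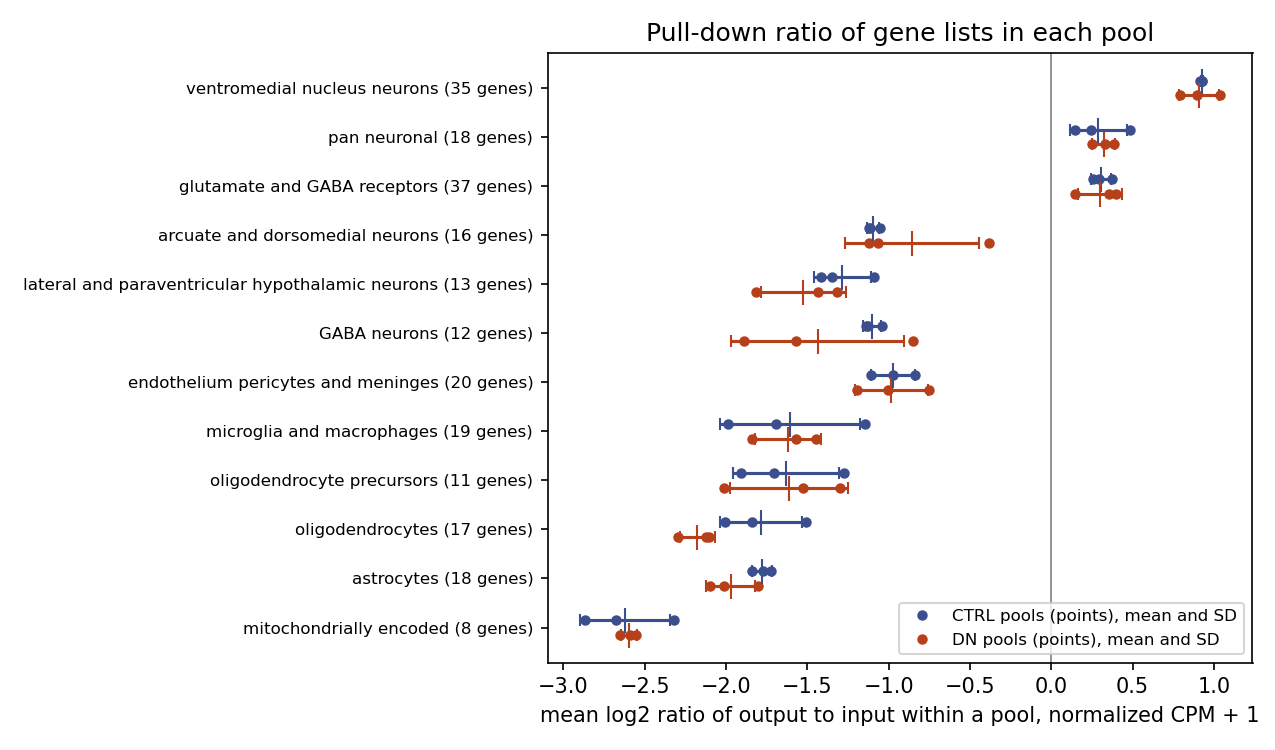
Mean log2 ratio of output to input within each pool (horizontal axis, normalized CPM plus 1) for 12 gene lists, with 1 point per pool and the mean and SD of 3 pools, CTRL in blue and DN in red. VMN neuron genes lie at 0.93 in CTRL and 0.91 in DN, and astrocyte genes at -1.78 and -1.97.

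The question the series title names is which translated transcripts differ when AMPK is blocked. Mitochondrially encoded genes were higher in DN outputs as a list, with 7 of 7 measured members positive and a median log2 fold change of 0.37 (camera adjusted p = 9.72e-05, but adjusted p = 0.566 with an estimated correlation). This list was depleted by the pull-down (median -3.04 in CTRL and -3.02 in DN, output against input). Its DN effect was similar in inputs, before the pull-down (median 0.38). The rise is therefore not read as a change in translated RNA of SF1 cells. None of the 7 passed over all genes by edgeR, and 1, mt-Nd2 of respiratory complex I, passed adjusted over the list alone (0.80 ± 0.20, from 707 ± 228 to 1234 ± 70.9 CPM), and was also the 1 member that DESeq2 called (adjusted p = 0.0401, the lowest of a range over the alternatives that reached 1). The genes of the AMPK catalytic subunits did not pass. Prkaa1 (ENSMUSG00000050697, chromosome 15, 5143861 to 5181899) had 34.6 ± 3.79 CPM in CTRL and 26.9 ± 5.01 in DN outputs (-0.37, 95% interval -1.04 to 0.31), and Prkaa2 (ENSMUSG00000028518, chromosome 4, 105029874 to 105109890) had 85.6 ± 12.5 and 91.4 ± 19.4 CPM (0.09, interval -0.39 to 0.58). Txn2, mitochondrial thioredoxin (ENSMUSG00000005354, chromosome 15, 77915047 to 77929006), had 5.87 ± 0.351 CPM in CTRL and 1.93 ± 0.976 in DN outputs, lower in all 3, at -1.60 ± 0.79 with adjusted p = 0.916. Rpl10a, Fos and Nr5a1 were at -0.32 (95% interval -1.41 to 0.77), -0.74 (-3.15 to 1.67) and -0.02 (-1.11 to 1.06).

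Of 13333 genes tested in outputs, 0 passed by edgeR, 721 had an unadjusted p below 0.05, and 58 passed by DESeq2 and 1 by limma-voom. The smallest unadjusted p belonged to Slc1a2, the gene limma-voom called, with 1414 ± 107 CPM in CTRL and 915 ± 61.1 in DN (-0.63 ± 0.11, adjusted p = 0.88). This glial gene was itself lower in DN outputs than in DN inputs (log2 fold change from -1.39 to -1.20 without 1 DN pool). Its fall between DN and CTRL is therefore not read as a change in translated RNA of SF1 cells. Rnf141, a ring finger protein, had 67.7 ± 3.6 and 20.1 ± 7.74 CPM (-1.75 ± 0.31), and Tox2, a transcription factor, 180 ± 10.7 and 308 ± 42.3 CPM (0.77 ± 0.16). Itga6, an integrin subunit, had 1.39 ± 0.516 and 11.8 ± 4.43 CPM (3.08 ± 0.70). Thg1l, Pcdhb9 and Tcte2 were at -6.85 ± 1.35, -4.83 ± 1.04 and -6.89 ± 1.49, with means of at most 7.55 CPM. Gm26658 had no count in CTRL outputs and was at least 252-fold higher in DN, Gm16353 had none in DN outputs and was at least 132-fold lower, and Spc25 had 1 count over the DN outputs against 445 over the CTRL outputs. Adjusted p was 0.88 for these 10 genes by edgeR, while DESeq2 called all 10, with adjusted p from 1.64e-05 for Tcte2 and Gm26658 to 0.00949 for Slc1a2 and Tox2, and the highest over the alternatives was 1. The groups were apart for 11.03% of genes, where chance gives 10%.

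Other fixed lists did not pass in outputs. Of 16 oligodendrocyte genes 14 were negative (median -0.28, adjusted p = 0.129), of 18 pan neuronal genes 15 were positive (median 0.19, adjusted p = 0.0527), and of 35 VMN neuron genes 26 were positive (median 0.27, adjusted p = 0.129). Among 16 astrocyte genes 1, Slc1a2, passed adjusted over the list alone (list adjusted p = 0.375). The lists of AMPK subunits, of thioredoxin and glutathione genes and of glucose transport and sensing had 6, 41 and 23 measured genes, none past the threshold by edgeR, and adjusted p = 0.854, 0.655 and 0.758. Interferon genes stood apart in CTRL pool 3, with Oasl2 at 27.9, 59.4 and 542 CPM in the 3 CTRL outputs. In the DN outputs Oasl2 had 111, 229 and 242 CPM, each above CTRL pools 1 and 2 and below CTRL pool 3. Without that pool the interferon list and the glial activation list were higher in DN outputs (adjusted p = 5.71e-05 and 5.22e-04, against 0.854 and 0.916 with all pools), and without CTRL pool 1 the mitochondrially encoded list no longer passed (adjusted p = 0.0813) while the pan neuronal list did (0.0067), as it did without DN pool 3 (0.0327).

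**Figure D3:**
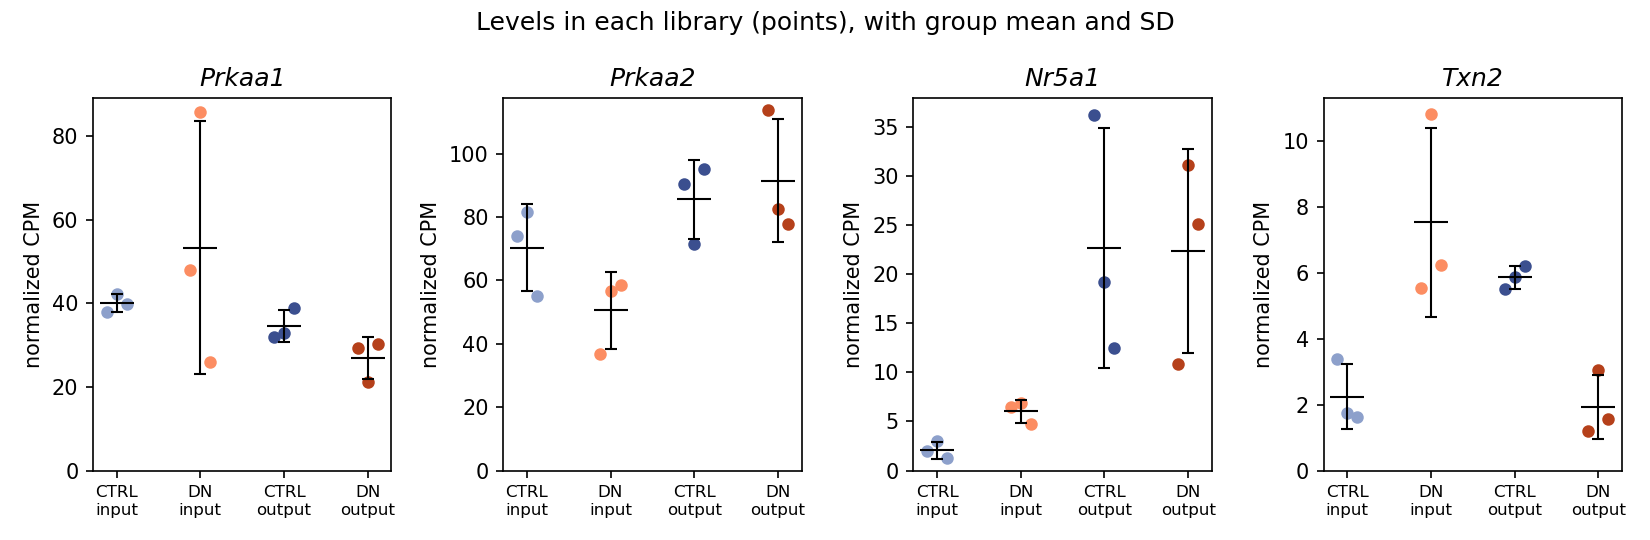
Normalized CPM (vertical axes) of Prkaa1, Prkaa2, Nr5a1 and Txn2 in the 4 groups, with 1 point per library and the mean and SD of 3 libraries. Txn2 lies at means of 2.25 and 7.53 in CTRL and DN inputs and of 5.87 and 1.93 in CTRL and DN outputs.

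The same contrast in inputs asked what differed in the tissue before the pull-down. In this contrast 1 mitochondrial gene passed. The small mitochondrial ribosomal RNA mt-Rnr1 (ENSMUSG00000064337) rose from 276295 ± 18064 to 392464 ± 39533 CPM (0.51 ± 0.06, adjusted p = 0.0479), higher in all 3 DN inputs. Of 8 mitochondrially encoded protein genes measured, 8 were positive with a median of 0.38, and 7 passed adjusted over the list alone though 0 passed over all genes by edgeR. The list rose in camera (adjusted p = 6.97e-06, but adjusted p = 0.844 with an estimated correlation and 0.182 with fry). Of these genes of respiratory complex I, mt-Nd2 was at 0.57 ± 0.10, mt-Nd5 at 0.38 ± 0.07, mt-Nd1 at 0.39 ± 0.08, mt-Nd6 at 0.46 ± 0.10 and mt-Nd4 at 0.41 ± 0.09. All of these but mt-Nd6 passed by edgeR with no filter on low counts and without CTRL pool 3, with a range over the alternatives from 3.55e-05 to 1 for mt-Nd2. The mt-Rnr1 call ended without DN pool 1 or 2 or CTRL pool 1 or 2 (adjusted p = 0.666, 0.82, 0.404 and 0.251), and over all alternatives its adjusted p ranged from 5.38e-23 to 1.

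Among 13221 genes, mt-Rnr1 was the 1 gene called by edgeR, 589 had an unadjusted p below 0.05, and DESeq2 and limma-voom called 2 and 8 genes, mt-Rnr1 not among them. Of the 8 by limma-voom, 7 were members of the mitochondrially encoded list, with adjusted p from 5.39e-04 for mt-Nd5 to 0.00312 for mt-Nd6. Others with small unadjusted p that did not pass by edgeR were Snhg11, a long noncoding RNA, with 276 ± 17.9 CPM in CTRL and 434 ± 60.2 in DN (0.65 ± 0.15), Irgq with 85.4 ± 12.2 and 44.3 ± 2.23 CPM (-0.94 ± 0.22), Prtg at -6.42 ± 1.41, and Adam5, which had no count in DN inputs and was at least 53.4-fold lower. Of these Prtg was 1 of the 2 genes DESeq2 called (adjusted p = 0.0012, the lowest of a range over the alternatives that reached 1). Without 1 replicate the log2 fold change of Prtg lay between -10.2 and -5.89. Txn2 had 2.25 ± 0.981 CPM in CTRL and 7.53 ± 2.86 in DN inputs (1.74, 95% interval 0.23 to 3.25, adjusted p = 0.997). Nr5a1 was at 1.54 (interval -0.05 to 3.13), Prkaa1 at 0.42 (-0.38 to 1.21) and Prkaa2 at -0.47 (-1.04 to 0.09). Rpl10a was at 0.22 (-1.47 to 1.92) and Fos at -0.53 (-2.97 to 1.92). Cytosolic ribosomal proteins (adjusted p = 0.0594), pan neuronal genes (0.116), VMN neurons (0.669), oligodendrocytes (0.721) and thioredoxin and glutathione genes (0.709) did not pass as lists. In CTRL inputs, too, Oasl2 stood apart in pool 3, with 18.0, 55.4 and 401 CPM, against 44.3, 96.9 and 193 CPM in the DN inputs. Without CTRL pool 3, the lists of interferon response, glial activation, microglia and cytosolic ribosomal proteins were higher in DN inputs (adjusted p = 2.14e-08, 1.97e-12, 0.0116 and 0.00355) and 8 genes passed. Without DN pool 3 the ribosomal list passed (0.0167). The groups were apart for 10.5% of genes, where chance gives 10%.

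Whether the DN virus was followed by a different change in pulled-down RNA than in input RNA was asked with the interaction of fraction and virus. Txn2 had the largest such difference among the 6 genes always named, at -3.34 ± 0.99 (95% interval -5.44 to -1.25), with adjusted p = 0.0227 over those 6 genes and 0.691 over all genes by edgeR, while DESeq2 called it over all genes (0.0339, the lowest of a range over the alternatives that reached 1). Itga6 had the smallest unadjusted p, with 11.1 ± 2.72 CPM in CTRL inputs, 2.07 ± 1.02 in DN inputs, 1.39 ± 0.516 in CTRL outputs and 11.8 ± 4.43 in DN outputs (5.50 ± 0.93, adjusted p = 0.283). Ppp1r8, a nuclear inhibitor of a protein phosphatase, and Zfp661, a zinc finger protein, were at 4.37 ± 0.90 and 4.87 ± 1.06, and Alox8, a lipoxygenase, Ccdc65 and Prob1 at -5.29 ± 1.10, -5.10 ± 1.12 and -7.06 ± 1.57, with adjusted p = 0.691 for each by edgeR. DESeq2 called these 6 genes too (adjusted p = 8.97e-08 for Itga6 and 5.13e-05 to 2.69e-04 for the others), and over the alternatives their adjusted p reached 0.985 for Itga6 and 1 for the others. Nr5a1, higher in outputs past the threshold in CTRL and not in DN by edgeR, differed by -1.56 ± 0.74 with adjusted p = 0.799, so a difference between CTRL and DN in its enrichment was not shown.

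Of 15011 genes 0 passed by edgeR, 933 had an unadjusted p below 0.05, and 91 passed by DESeq2 and 0 by limma-voom. With the pool as a block 0 genes passed. No list of 41 passed. Oligodendrocyte genes came nearest, with 15 of 17 negative and a median of -0.53 (adjusted p = 0.0699, and 0.601 with an estimated correlation), and passed with the pool as a block (0.0183) and without DN pool 2 (0.022) or CTRL pool 3 (0.0216), the last together with cytosolic ribosomal proteins (0.0216).

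The fitted DN effects in outputs and inputs were nearly uncorrelated across 12392 genes tested in both (Pearson r = 0.00907, Spearman 0.038). Unadjusted p was below 0.05 for 5.41% of genes in outputs and 4.46% in inputs. With effects so near chance, such a correlation cannot show whether true DN effects were alike or not. Genes are not independent replicates, so no p is given.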

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

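The tests of single libraries, of the number of nuclear genes at a common depth, of microglial RNA in the output library, of a wrong label and of relabelled pools were chosen only after the results were seen. Txn2 stood out because the effect of the DN virus differed between inputs and outputs in a test of that difference, which gave -3.34 ± 0.99 on the log2 scale, with adjusted p = 0.0227 over 6 genes and 0.691 over 15011 genes by edgeR, while DESeq2 called it over all genes (0.0339, in a range over the alternatives from 0.0339 to 1).

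For Txn2, 0% of its 4208 exon bases lay under exons of another annotated gene, which argues against reads shared with an overlapping gene. In all, 36 of 12392 genes were, like Txn2, lower in all DN outputs and higher in all DN inputs, where a random order of the libraries gives 31.0 if inputs and outputs are independent, and 30, 38 and 46 genes showed the reverse pattern, lower in both and higher in both. With whole pools relabelled, which keeps input and output together, 4 of 20 relabellings, the real one included, gave as many and the others ranged from 18 to 44, so chance spread between pools may account for the pattern. Txn2 was picked because it is remembered from the published study of these samples, so its small p over 6 genes is not independent evidence. An effect of the DN construct stays open and was not tested apart from these.

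Mitochondrially encoded genes had positive DN effects, with a median log2 fold change of 0.38 in inputs and 0.37 in outputs, but with an estimated correlation adjusted p was 0.844 and 0.566, and no list member passed over all genes by edgeR in the reported fit (589 and 721 genes at unadjusted p below 0.05), while limma-voom called 7 members in inputs and 0 in outputs, and DESeq2 0 and 1. In inputs the lowest median without 1 library was 0.31, which argues against a single library as the cause there. In outputs it was 0.16 without CTRL output 1, so a single library and a difference between groups cannot be told apart with 3 libraries a group. At 8.54 M nuclear counts every DN input had fewer genes with a count than every CTRL input, by 987 on average. Chance parts 3 libraries from 3 in either direction in 10% of cases. No test linked the number of genes to mitochondrial RNA. Less complex nuclear RNA therefore stays open as an explanation in inputs. In outputs the means differed by 517 and the libraries overlapped, which leaves it open there too. An effect of the DN construct stays open and untested.

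Interferon response genes were high in CTRL pool 3, with list medians of 2.29 in its input and 2.11 in its output on the log2 scale over the mean of the other CTRL libraries of that fraction. The smaller of these, 2.11, argues against 1 mislabelled library, since both libraries of the pool stood apart. In the input, 6 homeostatic microglia genes, all counted in the other CTRL inputs and all in the microglia list, had a median of 1.68, with Csf1r at 29.8 and P2ry12 at 30.5 CPM and 1 that went the other way, Fcrls at -0.97, so more microglia may account for part of the difference there. In the output their median was 0.0753, but these genes were low there (median 2.43 CPM, ratios from -0.65 to 0.96) and the microglia list of 16 genes scored 0.624 in this library against -0.433 and 0.044 in the other CTRL outputs, so microglial RNA carried through the pull-down and another source cannot be told apart. Beyond the content of microglia no biological explanation was tested, since no group of the design sets this pool apart. The CTRL pools also differed from DN pools. Scored as mean log2 deviation from the 6 libraries of a fraction, the interferon list was at -1.391, -0.642 and 1.607 in CTRL inputs and -0.532, 0.582 and 0.375 in DN inputs. In outputs it was at -1.118, -0.445 and 1.612 in CTRL and -0.71, 0.206 and 0.455 in DN.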

How the results depend on the processing

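Leaving out the mitochondrial genes was chosen after seeing the data. Counts not given here were within 1.5 times those reported, and the cause of the differences was not tested. In outputs, DESeq2 called 58 genes and limma-voom 1, and in inputs 2 and 8. In inputs, DESeq2 size factors, upper quartile scaling and a mean of at least 5 CPM gave 0 calls by edgeR. The block and 1 fit of 12 libraries gave 0 too (589 at unadjusted p below 0.05 in the reported fit). No filter gave 39, and leaving out a library 0 to 8. Leaving out mitochondrial genes also gave 0, but it removed mt-Rnr1, the only gene called, so that loss was fixed in advance. For output against input, DESeq2 gave 1172 genes in CTRL and 1124 in DN, no filter 903 and 976, 1 fit of 12 libraries 673 in DN, and leaving out a pool 45 to 214 and 115 to 148. The split in CTRL went from 240 higher and 191 lower to 160 and 194 with upper quartile scaling. For the interaction, DESeq2 gave 91 and no filter 54. With the block, outputs gave 0.

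Lists called with an estimated correlation were 0 in outputs, 0 in inputs, 6 in CTRL and 11 in DN. Fry gave 0 in outputs, and in inputs it called heat shock chaperones in place of the mitochondrially encoded list, which was lost. Without mitochondrial genes 0 lists were called in outputs and 0 in inputs. The only list called in each was the one left out, so this outcome was fixed in advance. Without 1 library the lists ranged from 1 to 3 in outputs and 1 to 5 in inputs. Without 1 pool, input and output together, they ranged from 0 to 2 in the interaction, where the block gave 1. The correlation between DN effects was 0.0275 at 5 CPM or more.

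Named genes were counted per comparison, so a gene may be counted more than once. For 147 such results past the threshold, 1362 of 1729 alternative values passed and 0 turned sign. For 93 others, 67 of 1274 passed and 15 turned sign. These were Nr5a1 in outputs (0.0501 with limma-voom, 0.0352 with the block, -0.33 to 0.49 without 1 library), Prkaa2 in outputs (-0.0888 to 0.195), Fos in inputs (-1.40 to 0.53), Rpl10a in inputs (-0.33 to 0.58), Prkaa1 in inputs (-0.12 to 0.74), Fos in DN output against input (-0.81 with limma-voom, -0.0109 with upper quartile scaling, -0.78 to 1.49 without 1 pool) and Fos in the interaction (-1.06 to 1.21 without 1 pool).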

Other observations

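The counts of genes in other splits of the libraries were chosen only after the results were seen. Further lists fell in DN outputs against inputs. Of 74 cytosolic ribosomal protein genes, 59 were negative with a list median of -0.52, while 1, Rpl15, rose by 1.42 ± 0.28. Of 45 thioredoxin and glutathione genes 2 were lower, Nqo1, a quinone reductase, at -7.51 ± 1.84 and Gpx8, a glutathione peroxidase of the endoplasmic reticulum, with 3.31 ± 2.0 CPM in inputs and no count in outputs. Without 1 DN pool adjusted p was 0.156 and 0.165 for Rpl15 (pools 1 and 3) and 0.0717 to 0.228 for Nqo1 and Gpx8 (any pool). With the pool as a block Nqo1 had adjusted p = 0.0858 (range over the alternatives 0.00124 to 0.228). These lists had adjusted p = 0.00584 and 0.0181, but adjusted p = 0.305 and 0.181 with an estimated correlation. Of 14 genes of arcuate and dorsomedial neurons, Prlr at 1.26 ± 0.20 and Pdyn, the dynorphin precursor, at 1.60 ± 0.34 were higher, and Otp at -2.81 ± 0.59 and Sst, somatostatin, at -1.27 ± 0.27 were lower (2 and 7 over the list alone, list adjusted p = 0.0293, but adjusted p = 0.197 with an estimated correlation). The list call ended without DN pool 1 or 2 (adjusted p = 0.0646 and 0.0756). Calls of its genes ended without pool 1 or 3 for Prlr (0.0607 and 0.0606) and Otp (0.238 and 0.183), and without any of the 3 for Pdyn and Sst (0.0674 to 0.207). With the block Otp had adjusted p = 0.0614 (range over the alternatives 9.78e-06 to 0.238).

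Each comparison of 3 against 3 libraries allows 10 splits, so no share under 0.1 can be reached. For output against input, the real split called 431 genes in CTRL and 441 in DN, as many as 1 split of 10 each, and the highest other split called 0 by edgeR, also among splits that part all pairs. Every other split there mixes outputs and inputs within a group, so the difference between fractions widens the spread within groups. Few calls are likely in such splits, so they do not test whether the pull-down had an effect. In outputs the real split called 0 genes, so it was fixed in advance that 10 of 10 splits called as many. The highest other called 2. In inputs 2 splits called as many as the real 1, and the highest other called 2. In the interaction the real split called 0 genes as well, so its 10 of 10 was also fixed in advance, and the highest other called 0. For lists, the real splits called 16 in CTRL and 20 in DN, against 12 and 10 in the highest other split, each as many as 1 split. The same mixing of outputs and inputs applies to these other splits. In outputs 9 of 10 and in inputs 8 of 10 splits called as many lists as the real split, which called 1, and the highest others called 4 and 6. In the interaction the real split called 0 lists, so it was again fixed in advance that 10 of 10 called as many.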
